A study of Mus musculus with 6 samples.

How the data were processed

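RNA was measured in hind limb skeletal muscle of 3 wild type mice and 3 mice deficient in the laminin alpha 2 chain, all 4 weeks old and each isolated on its own, per the labels. Total RNA was extracted with TRIzol and cleaned on RNeasy columns, and biotinylated cRNA was made from 1 ug, per the labels. Groups and replicate numbers were taken from the sample titles. The deposited values are linear signal intensity, 1 per probe set and array, for 45101 probe sets. The algorithm that made them is not given in the sources used here. From the values, the mean of each array without the lowest and highest 2% lay at 99.96 or 99.97, so the arrays had been scaled to a common level.

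Values were taken as log2(signal + 16). Array medians on this scale differed by 0.226 at most, below the 0.5 at which the arrays were to be centred, so no further normalization was applied. Of the probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Entrez identifiers matched 34754 probe sets to RefSeq genes of GRCm38.p6. Probe sets with a mean below the 40th percentile, a signal of 13.9, were left out, and each gene was read by its brightest probe set with exactly 1 symbol. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no block), with the data.table package, version 1.17.8. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene in the text is from limma.

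Gene lists were tested with limma's camera, with the correlation between genes preset at 0.01. The 33 lists with at least 3 tested members formed the family for adjustment. Of 710 different list genes, 624 were tested, 59 had no probe set with 1 symbol and 6 were matched through an older symbol. A list of sex-linked genes served as a check only. The rule for named genes was fixed before the data were examined. It took Lama2, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, and up to 4 members of each list with the smallest p. Predicted genes were skipped, 0 among the rises and 1 among the falls. Genes named outside the rule were chosen after their values were seen. Lists of brown adipocyte, hair follicle, imprinted and circadian clock genes were added after seeing the data.

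The steps were tested on 20 simulated data sets with the wild type means and the fitted variances of the 13113 genes, each with 200 changed genes. The gene test recovered 47.1% of genes changed 2-fold and 98.1% of those changed 4-fold, and 6.56% of its calls were unchanged genes. A list of 25 genes shifted by 0.5 on the log2 scale was found in 100% of the simulations. Of unchanged lists, 1.35% had a p under 0.05. The simulated genes were independent of each other, which measured genes are not. Alternatives were median centring, quantile normalization, other filters and pseudocounts, other uses of several probe sets, other priors, a 2-fold minimum, the replicate number as a block, each library left out and, for lists, an estimated correlation and fry. Added after seeing the data were a block for Y-linked transcripts (Eif2s3y signal above 100) and a fit without wild type replicates 1 and 2. In fits with libraries left out, the filter and the brightest probe set of each gene were chosen anew.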

Results

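Gene expression was measured in the hind limb skeletal muscle of 6 mice, all 4 weeks old. Of these, 3 were wild type and 3 were deficient in the laminin alpha 2 chain, a subunit of the laminin that links muscle fibres to their basement membrane. Each mouse was read on 1 Affymetrix array. The deposited value is a linear signal per probe set, with array medians between 20 and 26.1 signal units. The number of arrays limits the precision of every value. Means are given in signal units with their SD (n = 3 per group). Log2 fold changes are deficient minus wild type on the scale of log2(signal + 16), which understates the change of dim genes.

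The comparison asks how muscle deficient in the laminin alpha 2 chain differs from wild type muscle. Genes of developing and regenerating muscle were higher in deficient muscle as a list (adjusted p = 0.224 with an estimated correlation), where 12 of 25 rose, 1 fell and 12 did not pass. They were led by Sln, an inhibitor of the calcium pump, which rose from 221 ± 39.1 to 6131 ± 176 (adjusted p = 2.45e-06). Macrophage and matrix genes were higher as lists, with medians of 1.27 and 0.84 on the log2 scale (adjusted p = 0.388 and 0.519 with an estimated correlation). Genes of the respiratory chain, the tricarboxylic acid cycle and glycolysis were lower as lists, with medians of -0.45, -0.44 and -0.43 (adjusted p = 0.245, 0.224 and 0.224 with an estimated correlation). These calls were made with a preset correlation, and with an estimated one 0 of 33 lists were called. The 5 prime over 3 prime ratio of the actin control probe sets was lower in all 3 deficient libraries than in any wild type library. Those of the Gapdh, pyruvate carboxylase and transferrin receptor controls overlapped between the groups. Of 13113 genes tested, 362 changed, 170 higher and 192 lower, and 258 of them changed at least 2-fold. In all 362 the values of the groups did not overlap, as held for 3239 genes or 24.7% of those tested, where chance gives 10%. The count was 65, 72 and 219 without wild type replicates 1, 2 and 3, and 152, 80 and 665 without deficient replicates 1, 2 and 3. In a fit added after seeing the data it was 1160 with the presence of Y-linked transcripts as a block. Wild type replicates 1 and 2 carried hair follicle keratins. A fit without them leaves 1 wild type library, too few for a count of changed genes.

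Lama2, the gene of the laminin alpha 2 chain, fell from 390.2 ± 55.8 to 84.5 ± 54.7 (adjusted p = 0.0207), a log2 fold change of -2.17 (SE 0.374). The wild type libraries read 428.7, 415.6 and 326.2 and the deficient libraries 82, 31.1 and 140.4. The labels do not name the allele, and where the single Lama2 probe set lies relative to the altered part of the gene is not given in the sources used here. The call was lost with 1 library left out in 3 cases, with an adjusted p of 0.101 without wild type replicate 1, 0.0822 without wild type replicate 2 and 0.0585 without deficient replicate 1. Over all alternatives its adjusted p ran from 0.00325 to 0.396.

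The 12 largest rises included 6 genes of the regeneration and embryonic or fetal muscle list, Sln, Myh3, Myh8, Myl4, Tnnt2 and Ankrd1. The embryonic myosin heavy chain gene Myh3 rose from 32.9 ± 4.25 to 1156 ± 597 (adjusted p = 6.26e-04), and the perinatal Myh8 rose from 52.2 ± 47.4 to 1308 ± 693 (adjusted p = 0.00596). Myl4, a light chain of embryonic muscle, rose from 113 ± 35.5 to 1825 ± 763 (adjusted p = 6.26e-04), while the other of its 2 probe sets moved the opposite way. Mymx, which is needed for myoblast fusion, rose from 11 ± 7.24 to 258 ± 83.4 (adjusted p = 0.00107). The cardiac troponin T gene Tnnt2 rose from 85.4 ± 40.3 to 776 ± 296 (adjusted p = 0.0044), and Ankrd1 rose from 42.4 ± 12.6 to 538 ± 72.7 (adjusted p = 4.20e-04). The metallothionein genes, whose products bind metal ions, rose as well, Mt2 from 343 ± 33.3 to 3825 ± 1318 (adjusted p = 4.46e-04) and Mt1 from 555 ± 44.1 to 4175 ± 1657 (adjusted p = 0.00152). S100a4 rose from 279 ± 48 to 2205 ± 1021 (adjusted p = 0.00293) and Mpeg1, a macrophage gene, from 107 ± 13 to 877 ± 357 (adjusted p = 0.0023). Rrad rose from 24.9 ± 15.6 to 335 ± 262 (adjusted p = 0.0244), a call that was lost without 5 of the 6 libraries, with an adjusted p of 0.101 without wild type replicate 1, 0.0564 without wild type replicate 2, 0.064 without wild type replicate 3, 0.0523 without deficient replicate 1 and 0.101 without deficient replicate 2. Over all alternatives the adjusted p of Rrad ran from 7.61e-04 to 0.196.

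Ucp1, the uncoupling protein of brown adipocytes, had the largest fall, from 957 ± 566 to 33.4 ± 17.9 (adjusted p = 0.0044), a log2 fold change of -4.16. Several genes of enzymes and transporters fell too. Smox, the spermine oxidase gene, fell from 927 ± 319 to 138 ± 18.6 (adjusted p = 0.0029), while the other of its 2 probe sets moved the opposite way. Ddo, the gene of D-aspartate oxidase, fell from 279.7 ± 70.5 to 35.9 ± 8.72 (adjusted p = 0.00152), and Plcd4, a phospholipase C gene, fell from 1039.7 ± 289 to 176 ± 70.4 (adjusted p = 0.00576). Slc37a4, a glucose-6-phosphate transporter gene, fell from 1303 ± 144 to 306 ± 72 (adjusted p = 0.00205). Aqp4, a water channel of the fibre membrane, fell from 757 ± 176 to 163 ± 11.6 (adjusted p = 0.00183), Smco1 from 749 ± 174 to 149 ± 23.7 (adjusted p = 0.00205), and Aimp2, part of the tRNA synthetase complex, from 3296 ± 832 to 829.6 ± 232 (adjusted p = 0.00709). The brightest probe set of Ighm, the immunoglobulin M heavy chain gene, fell from 857 ± 71.4 to 165 ± 12.2 (adjusted p = 4.46e-04), but only 2 of its 6 probe sets moved that way. Mylk4, a myosin light chain kinase gene, fell from 1606 ± 786 to 367 ± 217 (adjusted p = 0.0316). Tchh, a hair follicle gene, fell from 181 ± 160.3 to 2 ± 1.85 (adjusted p = 0.0481), with 342.9, 178.8 and 22.3 in the wild type libraries. The call of Mylk4 was lost without 5 of the 6 libraries, with an adjusted p of 0.122 without wild type replicate 1, 0.0525 without wild type replicate 2, 0.0725 without wild type replicate 3, 0.0938 without deficient replicate 1 and 0.122 without deficient replicate 2 (9.80e-05 to 0.141 over all alternatives). That of Tchh was lost in 5 as well, with an adjusted p of 0.152 without wild type replicate 1, 0.171 without wild type replicate 2, 0.115 without deficient replicate 1, 0.168 without deficient replicate 2 and 0.0529 without deficient replicate 3 (0.00106 to 0.171 over all alternatives).

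**Figure D1:**
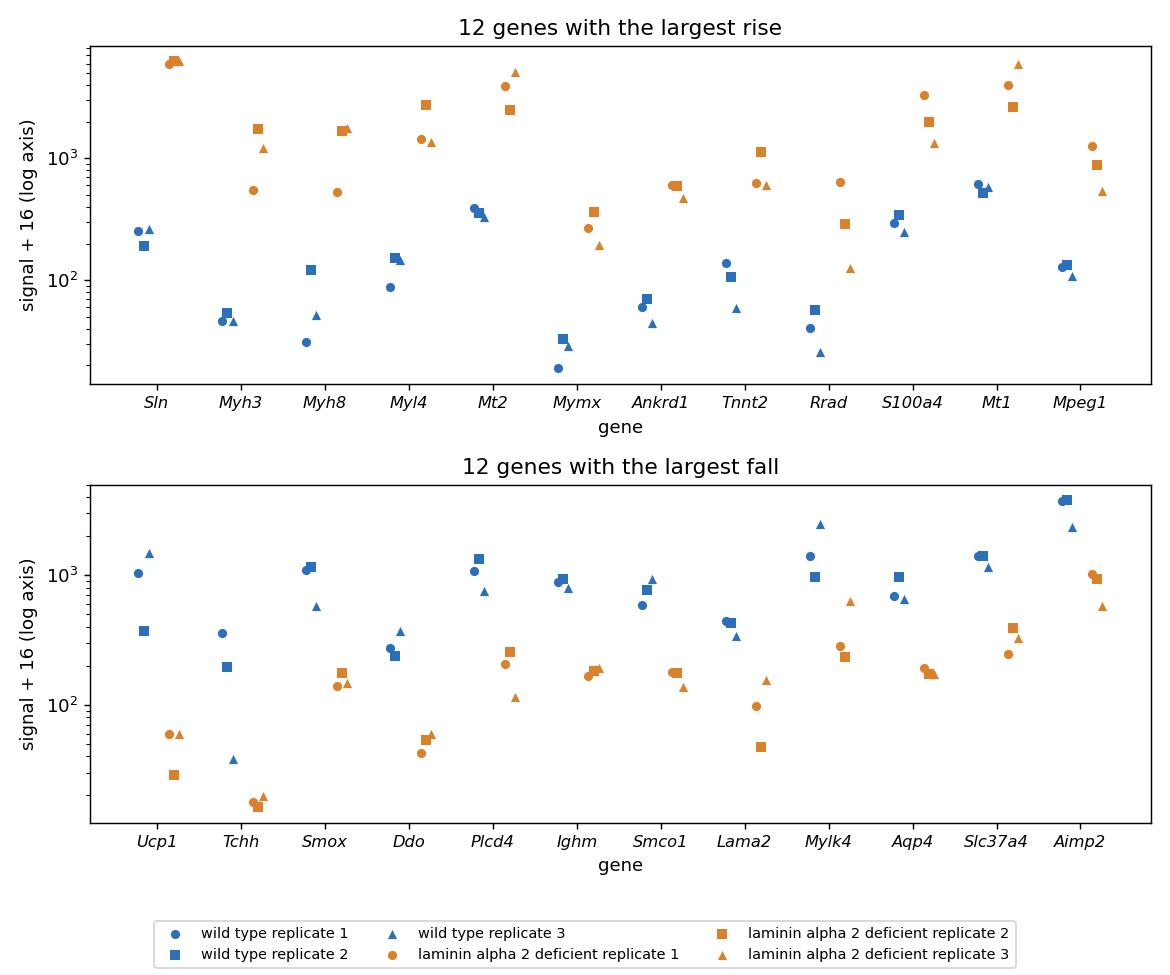
Signal of each library plus 16 (log axis) for the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom), with wild type in blue, deficient in orange and the symbol giving the replicate. Only genes whose groups did not overlap were eligible, so the gap between groups in every gene drawn follows from the choice. The wild type values of Tchh spread from 22.3 to 342.9.

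Of 33 gene lists fixed before the data were examined, 20 were called, 12 higher and 8 lower in deficient muscle. The calls rest on a correlation between genes preset at 0.01. Camera with an estimated correlation called 0 lists, with 6 at an unadjusted p under 0.05, and fry, which asks whether the genes of a list move one way on balance, called 8, with 11 at an unadjusted p under 0.05. Higher by fry were the regeneration, apoptosis and p53, TGF-beta and neuromuscular junction lists. The regeneration list shares Cdkn1a with the apoptosis list, and Chrna1 and Chrng among others with the neuromuscular junction list. Lower were the respiratory chain, tricarboxylic acid cycle, glycolysis, and T, B and NK cell lists. The other 12 called lists did not pass fry, among them macrophage markers (fry adjusted p = 0.112) and fibrillar collagens (0.286).

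Genes of muscle regeneration and of embryonic or fetal muscle had the highest median, 1.43 on the log2 scale. Of 25 tested, 12 rose, 1 fell and 12 did not pass, and 15 rose and 1 fell adjusted over the list alone. The list was called higher (camera adjusted p = 3.16e-14, and adjusted p = 0.224 with an estimated correlation), with Sln, Ankrd1, Myh3 and Myl4 at its smallest p values. Neuromuscular junction and denervation genes were higher too (camera adjusted p = 0.00283, and adjusted p = 0.224 with an estimated correlation). Their list shares Chrna1, Chrnd, Chrng, Myog and Ncam1 with the regeneration list, so the calls of both lists are not independent. Among their 15, 3 rose, 0 fell and 12 did not pass, and 5 rose and 0 fell adjusted over the list alone. Acetylcholine receptor subunit genes were among them: Chrna1 rose from 235 ± 51.8 to 660.4 ± 144 (adjusted p = 0.0161) and Chrng, the fetal subunit, rose from 8.57 ± 10.5 to 66.7 ± 27 (adjusted p = 0.0316). Runx1 rose from 22.6 ± 5.57 to 92.4 ± 31.1 (adjusted p = 0.0257), with 3 of its 5 probe sets moving that way. Of 20 apoptosis and p53 target genes, 3 rose, 0 fell and 17 did not pass, and 3 rose and 1 fell adjusted over the list alone. This list was called higher (camera adjusted p = 0.00191, and adjusted p = 0.224 with an estimated correlation). Eda2r, a gene of the TNF receptor family, rose from 71.3 ± 5.2 to 283 ± 15.8 (adjusted p = 0.00194), the cell cycle inhibitor gene Cdkn1a from 182 ± 50.8 to 1157 ± 701 (adjusted p = 0.015) and Pmaip1 from 11.9 ± 7.19 to 62.7 ± 18.6 (adjusted p = 0.0282). The following calls were lost with 1 library left out, given with the highest adjusted p: Chrna1 (0.0736 without deficient replicate 2), Chrng (0.122 without deficient replicate 2), Runx1 (0.115 without wild type replicate 1), Cdkn1a (0.0644 without deficient replicate 2) and Pmaip1 (0.115 without deficient replicate 2).

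Macrophage and monocyte markers were higher, with a positive fold change in 24 of 24, also under median centring and quantile normalization. Of these, 6 rose, 0 fell and 18 did not pass, and 18 rose and 0 fell adjusted over the list alone (camera adjusted p = 5.89e-13, and adjusted p = 0.388 with an estimated correlation). Besides Mpeg1, the galectin gene Lgals3 rose from 248 ± 70 to 1849.7 ± 897 (adjusted p = 0.00588), Gpnmb from 45.6 ± 1.95 to 233 ± 84.8 (adjusted p = 0.00842) and the NADPH oxidase gene Cybb from 102 ± 7.69 to 343 ± 106 (adjusted p = 0.0151). Of 14 complement genes, 1 rose, 0 fell and 13 did not pass, and 6 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00283, and adjusted p = 0.486 with an estimated correlation). The gene that rose was C1ra, from 182 ± 21.5 to 337 ± 18.4 (adjusted p = 0.0419). Lost with 1 library left out, with the highest adjusted p, were the calls of Gpnmb (0.0541 without deficient replicate 2), Cybb (0.0789 without wild type replicate 1) and C1ra (0.162 without wild type replicate 1).

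Fibrillar collagens and interstitial matrix genes were called higher (camera adjusted p = 4.87e-08, and adjusted p = 0.519 with an estimated correlation). Of 26 tested, 5 rose, 0 fell and 21 did not pass, and 9 rose and 0 fell adjusted over the list alone. Postn, which encodes periostin, rose from 1408 ± 749.8 to 5893 ± 1606 (adjusted p = 0.0215), Col8a1 from 173 ± 61.4 to 1106 ± 584 (adjusted p = 0.0243) and the elastin gene Eln from 281 ± 112 to 740.2 ± 169 (adjusted p = 0.0423). Of 19 matrix proteases and inhibitors, 5 rose, 0 fell and 14 did not pass, and 8 rose and 0 fell adjusted over the list alone (camera adjusted p = 5.64e-04, and adjusted p = 0.477 with an estimated correlation). The cathepsin gene Ctss rose from 349.5 ± 47.6 to 1914 ± 889 (adjusted p = 0.00858), the gelatinase gene Mmp2 from 732 ± 170.3 to 1680.4 ± 147 (adjusted p = 0.0194) and Mmp14 from 199 ± 86.5 to 597 ± 14.6 (adjusted p = 0.0286). TGF-beta signalling and profibrotic factors were called higher (camera adjusted p = 0.00233, and adjusted p = 0.28 with an estimated correlation). Among their 18, 1 rose, 0 fell and 17 did not pass, and 2 rose and 0 fell adjusted over the list alone. Ccn2, which encodes connective tissue growth factor, was the gene that rose, from 258 ± 42.3 to 832 ± 59.7 (adjusted p = 0.00374). Of 15 fibroblast and fibro-adipogenic progenitor markers, 1 rose, 0 fell and 14 did not pass, and 2 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.641 with an estimated correlation). S100a4 was the gene that rose. That list lost its call without wild type replicate 3 (adjusted p = 0.0823), deficient replicate 1 (0.0748) and deficient replicate 2 (0.134), in a range of 7.51e-05 to 0.641 over all alternatives. The following calls were lost with 1 library left out, given with the highest adjusted p: Postn (0.101 without deficient replicate 2), Col8a1 (0.106 without deficient replicate 2), Eln (0.168 without deficient replicate 2), Ctss (0.0554 without deficient replicate 2), Mmp2 (0.0865 without deficient replicate 2) and Mmp14 (0.107 without deficient replicate 2).

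Slow fibre genes were higher and fast fibre genes lower as lists. Of 12 slow fibre genes, 3 rose, 0 fell and 9 did not pass, and 8 rose and 0 fell adjusted over the list alone (camera adjusted p = 9.39e-07, and adjusted p = 0.388 with an estimated correlation). Myoz2 rose from 1968 ± 331 to 4245 ± 565 (adjusted p = 0.015), the slow troponin I gene Tnni1 from 584 ± 87.5 to 1538 ± 452 (adjusted p = 0.0199) and the calsequestrin gene Casq2 from 404 ± 75 to 1233 ± 391 (adjusted p = 0.02). By limma, 0 of 16 fast fibre genes passed, also adjusted over the list alone, with 5 at an unadjusted p under 0.05. Their list was called lower (camera adjusted p = 0.00159, and adjusted p = 0.641 with an estimated correlation), with a median of -0.22. Myoz1 stood at 7487 ± 378 in wild type and 5315 ± 769 in deficient muscle (adjusted p = 0.0888). This call was lost under quantile normalization (adjusted p = 0.0804) and without deficient replicate 1 (0.0718), in a range of 3.27e-05 to 0.641 over all alternatives. Of 17 genes of creatine metabolism, calcium handling and excitation-contraction coupling, 0 rose, 2 fell and 15 did not pass, and 0 rose and 6 fell adjusted over the list alone (camera adjusted p = 9.42e-06, and adjusted p = 0.388 with an estimated correlation). Stac3 fell from 1729.9 ± 324 to 724 ± 157 (adjusted p = 0.0198) and the mitochondrial creatine kinase gene Ckmt2 from 7221 ± 301 to 4441 ± 525 (adjusted p = 0.0266). Lost with 1 library left out, with the highest adjusted p, were the calls of Myoz2 (0.0619 without wild type replicate 2), Tnni1 (0.096 without wild type replicate 1), Casq2 (0.0883 without deficient replicate 2), Stac3 (0.093 without wild type replicate 1) and Ckmt2 (0.128 without wild type replicate 2).

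Genes of energy metabolism were lower as lists. All 42 tested genes of the respiratory chain and ATP synthase had a negative fold change, and 40 of them under quantile normalization. Of the 42, 0 rose, 5 fell and 37 did not pass, and 0 rose and 31 fell adjusted over the list alone (camera adjusted p = 9.85e-19, and adjusted p = 0.245 with an estimated correlation). The cytochrome c oxidase gene Cox7a1 fell from 4418 ± 54 to 2414 ± 166 (adjusted p = 0.0119) and the complex I gene Ndufa10 from 2894 ± 248 to 1805 ± 91.6 (adjusted p = 0.0395). Of 16 tricarboxylic acid cycle genes, 0 rose, 2 fell and 14 did not pass, and 0 rose and 11 fell adjusted over the list alone (camera adjusted p = 3.86e-07, and adjusted p = 0.224 with an estimated correlation). Idh3a, an isocitrate dehydrogenase subunit, fell from 4858 ± 369 to 2321 ± 362 (adjusted p = 0.0104) and Suclg1 from 2753 ± 141 to 1474 ± 230.4 (adjusted p = 0.0216). Glycolysis and glycogen genes were called lower (camera adjusted p = 3.19e-09, and adjusted p = 0.224 with an estimated correlation). Among their 23, 0 rose, 5 fell and 18 did not pass, and 0 rose and 10 fell adjusted over the list alone. Gpd1 fell from 2111 ± 396 to 823 ± 92.3 (adjusted p = 0.00935), the phosphorylase kinase gene Phkg1 from 1480.0 ± 137 to 564 ± 137 (adjusted p = 0.0119) and the muscle glycogen phosphorylase gene Pygm from 6362 ± 540.2 to 3791 ± 749 (adjusted p = 0.0419). By limma, 0 of 23 genes of fatty acid uptake and oxidation passed, also adjusted over the list alone, with 5 at an unadjusted p under 0.05. Their list was called lower (camera adjusted p = 2.28e-04, and adjusted p = 0.562 with an estimated correlation). Hadhb stood at 3178 ± 521 in wild type and 2211 ± 367 in deficient muscle (adjusted p = 0.153). The 5 prime over 3 prime ratio of the actin control probe sets was 1.15, 1.05 and 1.04 in the wild type and 0.819, 0.51 and 0.573 in the deficient libraries. The same ratio overlapped between the groups for the Gapdh, pyruvate carboxylase and transferrin receptor controls. Besides Ucp1, 6 of 7 other brown adipocyte markers, listed after the data were seen, had a negative fold change. Their median was -0.90 over the 7 (camera p = 0.00138, and p = 0.168 with an estimated correlation). Of all 8 with Ucp1, 0 rose, 2 fell and 6 did not pass by limma. Macrophage markers were higher as a list. The following calls were lost with 1 library left out, given with the highest adjusted p: Cox7a1 (0.0756 without wild type replicate 1), Ndufa10 (0.163 without wild type replicate 1), Idh3a (0.0619 without wild type replicate 2), Suclg1 (0.107 without wild type replicate 1), Gpd1 (0.0628 without wild type replicate 1), Phkg1 (0.066 without wild type replicate 2) and Pygm (0.14 without deficient replicate 2).

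**Figure D2:**
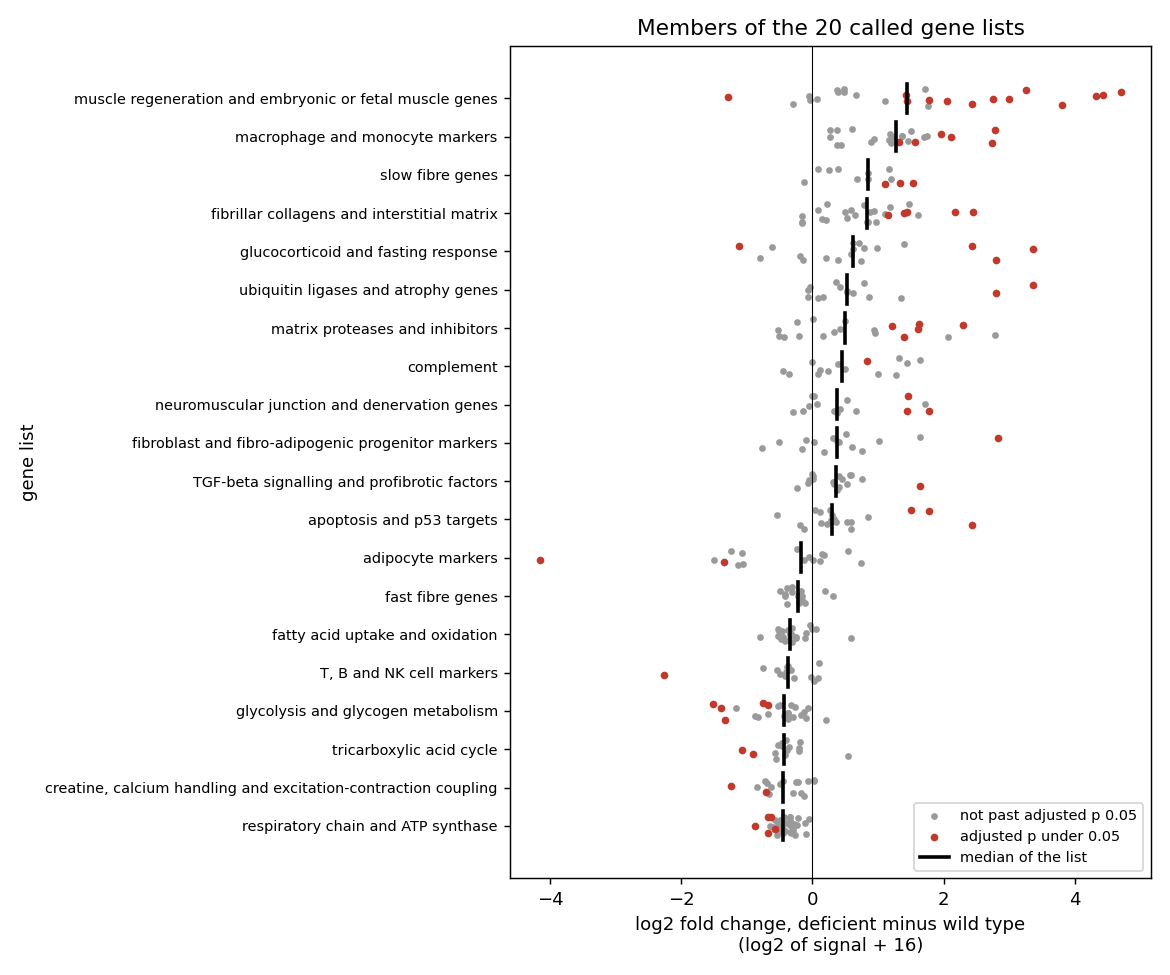
Log2 fold change, deficient minus wild type, of every tested member of the 20 called gene lists, with genes past an adjusted p of 0.05 in red, the others in grey and each list's median as a black bar. The regeneration list has the highest median, 1.43, and the respiratory chain list the lowest, -0.45.

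Of 15 ubiquitin ligase and atrophy genes, 2 rose, 0 fell and 13 did not pass, and 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 6.51e-04, and adjusted p = 0.584 with an estimated correlation). Those that rose were Mt1 and Mt2, which encode metallothioneins and no ubiquitin ligase. Of 18 glucocorticoid and fasting response genes, 3 rose, 1 fell and 14 did not pass, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00702, and adjusted p = 0.641 with an estimated correlation). Mt1, Mt2 and Cdkn1a rose, and the kinase gene Sgk1 fell from 2745 ± 283 to 1253 ± 81.9 (adjusted p = 0.00739). Cdkn1a lost its call without some libraries (adjusted p up to 0.0644, without deficient replicate 2). Without deficient replicate 3 both list calls were lost, the atrophy list at an adjusted p of 0.117 (2.52e-06 to 0.584 over all alternatives) and the glucocorticoid list at 0.642 (9.68e-05 to 0.642). The glucocorticoid call was also lost without wild type replicates 1 and 2 (adjusted p = 0.366). Deficient replicate 3 stood apart in genes chosen after their values were seen. The ubiquitin ligase gene Fbxo32 read 2814.5 there and 143 to 248.4 elsewhere, and Trim63 4565.7 and 1016.1 to 1566.4. Pdk4, a kinase gene induced by fasting, read 6603.2 there and 779.8 to 1235.7 elsewhere, and the fatty acid synthase gene Fasn 147.8 and 1913 to 3794.9.

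Of 16 adipocyte markers, 0 rose, 2 fell and 14 did not pass, and 0 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.641 with an estimated correlation). Both genes that fell mark brown adipocytes, Ucp1 and Cidea, the latter from 792 ± 228 to 296 ± 39.5 (adjusted p = 0.021). The list's call was lost without wild type replicate 3 (adjusted p = 0.186) and deficient replicate 3 (0.121), under quantile normalization (0.0751), with the filter at the 60th percentile (0.0529) and with the mean of all probe sets (0.0764). Over all alternatives its adjusted p ran from 1.75e-05 to 0.641, and the call of Cidea was lost with 1 library left out (adjusted p up to 0.104, without wild type replicate 1). Of 14 T, B and NK cell markers, 0 rose, 1 fell and 13 did not pass, and 0 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00227, and adjusted p = 0.224 with an estimated correlation). The gene that fell was Ighm, whose probe sets did not move together.

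The other 13 lists were not called. Among laminin chains other than Lama2, which the list leaves out, and other basement membrane components, 0 of 18 passed by limma, also adjusted over the list alone, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.704). Lama4 stood at 321 ± 69.1 in wild type and 584 ± 163 in deficient muscle (adjusted p = 0.124). Among laminin receptors, the dystrophin-glycoprotein complex and integrin partners, 0 of 27 passed, while 2 rose and 1 fell adjusted over the list alone, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.587). Itga7 stood at 182 ± 8.63 in wild type and 321 ± 36.9 in deficient muscle (adjusted p = 0.057). Among stress response genes the small heat shock protein gene Hspb7 rose from 943 ± 142 to 2379.6 ± 279.7 (adjusted p = 0.00634) and the superoxide dismutase gene Sod2 fell from 2304 ± 63.8 to 1297 ± 114 (adjusted p = 0.0216) (camera adjusted p = 0.587 for the list). Thbs4 rose from 861 ± 233 to 3119 ± 936 (adjusted p = 0.0119) in the tendon, cartilage, bone and skin list (camera adjusted p = 0.203). Nr4a1 fell from 1198 ± 180.1 to 410.3 ± 62.5 (adjusted p = 0.00576) in the immediate early list (camera adjusted p = 0.704). The camera adjusted p was 0.154 for cell cycle, 0.233 for Schwann cell, 0.242 for interferon and MHC class I, and 0.249 for endothelial and pericyte genes. It was 0.299 for neutrophil and mast cell, 0.587 for proteasome, 0.611 for autophagy and lysosome and 0.86 for erythroid genes. In the immediate early and erythroid lists the median, the mean and the test differed in sign. Without 1 library, calls appeared for the cell cycle list (adjusted p = 2.79e-04 without wild type replicate 2 and 0.00311 without deficient replicate 3, 6.83e-05 to 0.92 over all alternatives). The neutrophil list was called without deficient replicate 3 (0.00523, 0.00523 to 0.955 over all alternatives). The tendon list was called without wild type replicate 3 (0.0144) and deficient replicate 2 (0.0472, 0.0144 to 0.976 over all alternatives). Lost with 1 library left out, with the highest adjusted p, were the calls of Sod2 (0.368 without wild type replicate 2) and Thbs4 (0.0662 without deficient replicate 2). With a library left out the brightest probe set was chosen anew, and Sod2 has 4 above the filter. Its 0.368 may therefore come from another probe set than that of the main fit.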

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

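Both results here were chosen for testing after their values were seen. The actin control probe sets, which no comparison used, had a higher 3 prime over 5 prime signal ratio in deficient muscle, 1.643 ± 0.381 (SD, n = 3, lowest 1.22), than in wild type, 0.928 ± 0.0522 (n = 3, highest 0.965). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The ratios of the Gapdh, pyruvate carboxylase and transferrin receptor controls overlapped between the groups.

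Probe sets without exactly 1 gene symbol were left out of the gene test. Of 3945 above the filter, 32 changed, 16 higher and 16 lower in deficient muscle (limma, adjusted over these probe sets).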

How the results depend on the processing

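Of 75 named genes past the threshold, 74 kept their direction in every alternative in which they were measured. The exception was Slc16a10, at a log2 fold change of -1.38, and of 0.0407 without wild type replicates 1 and 2. The latter was read on another probe set, as the brightest one was chosen anew. On the probe set of the main fit, wild type replicate 3 read 157.8 and the deficient libraries 38.9 to 73.8. Without each library in turn, 28 of the 75 stayed past the threshold. Of the 24 genes with the largest changes, 20 did, and Lama2, Rrad, Tchh and Mylk4 did not. The 362 changed genes (170 higher, 192 lower) were 214 (106 and 108) with no filter on dim probe sets, where more genes were tested, and 171 (92 and 79) by eBayes without trend. They were 1160 (550 and 610) with Y-linked transcripts as a block and 19 (15 and 4) without wild type replicates 1 and 2, where the lone wild type sample is assumed to vary like the deficient ones, both chosen after seeing the data. Centring on medians left 99 higher, and a fold change of at least 2 left 115 lower. Leaving out 1 library gave 65 to 665 changed genes, 33 to 391 higher and 26 to 274 lower. With the replicate number as a block 864 genes were called (421 higher, 443 lower), all 362 among them. The labels name no pairing, so the main fit had no block. Same-numbered samples' deviations correlated at 0.15, 0.0682 and 0.301, and 4 of 6 samples correlated best with their own number. A pairing by number therefore cannot be excluded, nor can it be told apart from the presence of Y-linked transcripts. In both groups only replicate 3 lacked them, with Eif2s3y at 10.7 in wild type and 9.1 in deficient muscle. The other libraries read 414.6 to 573.7. Of the 20 called lists (12 higher, 8 lower), 18 kept their call over normalizations, filters, pseudocounts, probe set rules and priors. Camera with an estimated correlation called 0 (0 higher, 0 lower, 6 at an unadjusted p under 0.05), and fry 8 (4 higher, 4 lower). Without wild type replicates 1 and 2, calls appeared for the cell cycle, interferon and MHC class I, stress, laminin chain and immediate early lists. The wild type library left, replicate 3, read 128.3 for H2-K1 and 78.3 for H2-D1, which the interferon and MHC class I list holds. The deficient libraries read 1638.9 to 2181.3 and 1261.9 to 1545.3. Beyond the number of genes tested without a filter, the cause was not tested. Signals near the filter at 13.9 limit what can be said of dim genes.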

Other observations

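Every test in this part was chosen after the result it bears on was seen, and its bounds were set with those values known. Several imprinted genes were higher in deficient muscle. Of 33 listed after the data were seen, 23 were tested, and 8 rose and 0 fell by limma: Dlk1, Grb10, Igf2, Mirg, Rian, Peg3, Plagl1 and Meg3. Dlk1 rose from 39.6 ± 14.6 to 356 ± 92.9 (adjusted p = 0.00152), Igf2, a fetal growth factor gene, from 536 ± 113 to 2391 ± 1080.4 (adjusted p = 0.0111) and Grb10 from 672 ± 7.96 to 1483 ± 169.9 (adjusted p = 0.0101). The regeneration list holds 4 of the tested genes. Without those, 6 of 19 rose, with a median log2 fold change of 0.15. Camera then gave p = 0.00144, and p = 0.0734 with an estimated correlation. As the list was chosen after the data were seen, camera on it cannot test a rise of imprinted genes as a group. Its p also rests on the correlation assumed. Lost with 1 library left out, with the highest adjusted p, were the calls of Grb10 (0.0616 without wild type replicate 1), Mirg (0.0572 without deficient replicate 2), Rian (0.103 without wild type replicate 2), Peg3 (0.125 without wild type replicate 2), Plagl1 (0.142 without wild type replicate 1) and Meg3 (0.156 without wild type replicate 2). Over all 23 tested genes, under the same limits, camera gave p = 3.06e-05, and p = 0.0498 with an estimated correlation.

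Hair follicle genes were highest in wild type libraries. In 12 of 13 tested, wild type replicates 1 and 2 both exceeded every other library, and Krt25 read 653.3, 244.5 and 17.1 in wild type and 3.4 to 20.2 in deficient muscle. Camera gave the hair follicle list p = 2.66e-09, and p = 0.125 with an estimated correlation. By limma 0 of 16 tested circadian clock genes passed, with 3 at an unadjusted p under 0.05. Their list did not pass the camera test either, with a p of 0.382, and 0.651 with an estimated correlation.

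The real grouping gave 362 changed genes, and the highest of the other splits of the 6 samples into 3 and 3 gave 2, so 1 of 10 splits reached the real count. For gene lists the real grouping gave 20 calls and the highest other split 21. In all, 3 of the 10 splits called at least as many lists. These were the real one, wild type replicate 1 with deficient replicates 1 and 3 (21), and wild type replicates 1 and 3 with deficient replicate 3 (20). The splits are too few for a share under 0.05.

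Energy metabolism lists and Ucp1 were lower in deficient muscle, and less brown fat carried over may account for Ucp1. The other 7 brown adipocyte markers tested had a median log2 fold change of -0.90. That lay below all 10000 random lists matched on expression (percentile 0). Those lists were drawn gene by gene and ignore correlation between markers, so the percentile cannot measure how rare the median is. For the markers camera gave p = 0.00138, and p = 0.168 with an estimated correlation. For the respiratory chain and tricarboxylic acid cycle a fit with the Ucp1 signal as a covariate cannot decide. Ucp1 read 356.7 to 1481.2 in wild type and 12.7 to 43.8 in deficient libraries, so it nearly followed the grouping. Their difference of -0.43 (SE 0.0612) was -0.39 with the covariate (SE 0.119, 95% interval -0.76 to -0.0063, and -0.61 to -0.33 without any 1 library). The interval held 0 with the log2 Ucp1 signal instead (-0.45, SE 0.222, -1.16 to 0.25). Over all 3 lists the difference of -0.46 (SE 0.0744) was -0.39 with the covariate (SE 0.14, -0.84 to 0.052). Brown fat stays open as a cause for the respiratory chain and tricarboxylic acid cycle. For glycolysis it cannot be told apart either with so few libraries. There the difference of -0.56 (SE 0.122) was -0.42 with the covariate (SE 0.221, -1.12 to 0.29). A lower share of fibre RNA stays open as well. The 3 lists differed from calcium handling genes by only -0.03 (SE 0.0721). From fast fibre genes they differed by -0.25 (SE 0.0864, 95% interval -0.49 to -0.0074). Macrophage markers parted from the mean of 8 other cell type lists by 1.34 (SE 0.369, and 1.00 to 1.54 without any 1 library). That contrast cannot decide, as it reads no fibre genes and added macrophages would themselves lower the fibre share. More macrophages and the deficiency itself stay open as untested.

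Deficient replicate 1 held both Xist, at 396.3 signal units, and Y-linked transcripts, with Eif2s3y at 414.6. The other libraries with Y-linked transcripts read at most 19.1 for Xist. RNA of a female and a male mouse in one library may be the source: its Xist was 26.4% of the mean of the 2 libraries without Y-linked transcripts, which predicts a Y-linked level of 73.6%, and the measured level was 83.2% of the other libraries' (SD 8.12). With 3 such libraries it cannot be told apart from either the prediction or the full level, and no biological explanation was tested.

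The MHC class I genes H2-K1 and H2-D1 differed among wild type libraries. The brightest H2-K1 probe set read 2480.3, 911.7 and 128.3 in wild type and 1638.9 to 2181.3 in deficient muscle, while an H2-D1 probe set ran the other way, at 40.8, 386.5 and 761.8, and 18.3 to 47.2 in deficient muscle. From wild type replicate 1 to 3 the probe sets of both genes moved by -4.76 to 3.775 on the log2 scale, and the rise of 3.775 argues against lower class I expression in wild type replicate 3, as B2m moved by -0.22. Different MHC haplotypes, each read by its own probe sets, are a candidate explanation, and probe sets shared with other class I genes were not tested.

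Changed genes lay near Lama2 on its chromosome. Among the 100 nearest tested genes, 50 on either side in GRCm38.p6, 6 changed, or 6% against 2.73% of other genes (two-sided Fisher's exact p = 0.0581). They were Plagl1, Sgk1, Ccn2, Slc16a10, Ddo and the predicted gene Gm16364. Of these 6, the calls lost with 1 library left out, given with the highest adjusted p, were Plagl1 (0.142 without wild type replicate 1), Slc16a10 (0.397 without wild type replicate 3) and Gm16364 (0.122 without deficient replicate 2). Without wild type replicate 3 the probe set was chosen anew, so the value of Slc16a10 may come from another one than in the main fit. Variants carried along with the altered allele may contribute, but this test did not pass 0.05.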
